A study of Homo sapiens with 4 samples.

How the data were processed

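Input RNA and RNA recovered with a Flag antibody were sequenced from cultured HEK293T cells. Per the labels' protocols, cells were cross-linked with 0.75% formaldehyde (for 10 min in the series' design text), lysed, sonicated for 10 cycles and incubated with the Flag antibody and magnetic protein A/G beads, and libraries were made with a stranded mRNA kit for an Illumina instrument. Whether poly(A) selection or rRNA removal came before library construction is not given in the sources used here. The deposited table holds 1 TPM value per gene symbol and library, rounded to 2 decimals. STAR, RSEM 1.2.31 and GRCh38 are named in the submitters' processing notes; the annotation and settings are not given in the sources used here. TPM divides by transcript length, which gives short RNAs large values and makes them sensitive to few reads, and it sums to a fixed total over all features, so a rise of a few RNAs lowers the values of all others. The sums of the listed genes differed between libraries, so the authors scaled their TPM over more features than the table lists, and the unlisted part was not used here. RSEM shares reads among near-identical sequences by estimate, so copies of U1, 5S, 7SL, snoRNA, miRNA and histone genes, and the overlapping rRNA entries, are uncertain.

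Samples were grouped by their titles into control input and control Flag RIP, with 2 libraries each, and every column of the table was matched to a title. No pair of columns held identical values throughout. The deposited TPM values were transformed to log2(TPM + 1) without further scaling, genes with a mean of at least 1 TPM over the 4 libraries were kept, and limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, no block) gave log2 fold changes of Flag RIP minus input, with Benjamini-Hochberg adjustment over all genes tested. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. In this fit limma's prior degrees of freedom were infinite. Its SE and p-values therefore rest on the trend over genes of similar level, not on the spread of the gene's own replicates. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it. Fry tests whether a list's genes move, on balance, one way and does not compare the list with other genes. The 31 lists, the tests and the rule for named genes were fixed before the data were examined.

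The rule named, per direction, up to 12 genes with the largest change among those past the threshold with a mean of at least 5 TPM and no overlap between groups; per list up to 4 members past the threshold or, where fewer than 2 passed, those with the highest mean; METTL3, METTL14, METTL16, MAT2A and MALAT1; the 5 highest genes per group; and the genes behind counts of 5 or fewer. Genes outside it are said to have been chosen after their values were seen. All genes that the rule names were carried through the alternatives fixed beforehand; 1 of them is not reported here.

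Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, at least 1 TPM in every library, quantile normalization, median centring, rescaling without small RNA genes and the 20 highest genes, the replicate number as a block, eBayes without trend or robust, each library left out in turn, and stricter thresholds. After the data were seen, 6 further settings were tried: TPM scaled per library over genes other than small RNAs and the 20 highest; listed genes rescaled to 1 total; and median centring combined with the block, with a pseudocount of 0.1, or without either Flag RIP library. These 6 were first run for all lists and named genes; only the counts and the 4 called lists are reported from them, a restriction made after their values were seen. The split of small RNAs into 7 classes was also made then. On simulated data for this comparison, with 200 of 9832 genes changed per round over 10 rounds, the test without centring recovered 0% of log2 changes of 1, 5.50% of 2 and 99.5% of 4, and 55% of -1 and 89.2% of -2; with median centring these were 81%, 96.5%, 99.5%, 65.5% and 61.8%. Unchanged genes called averaged 10.2 and 7.9 per round. Simulated spreads were drawn around the trend of the centred fit, with more degrees of freedom than the 2.84 that the centred data gave. In the data, the 31 genes called higher without centring had a centred median change of 2.28, yet 0 genes were called after centring. Recovery in the data can thus be lower, and 0 calls do not show that such changes are absent.

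Coordinates, gene types, GC content and lengths of the longest transcript came from GENCODE release 29 on GRCh38, matched by gene symbol for 23870 of the 26830 symbols (89.0%) and 9485 of the 9832 tested genes (96.5%); that annotation can differ from the authors'. For a second length test, added after the first was seen, the principal isoform by APPRIS class, transcript support level and length was used. GC and length trends were removed with lowess (fraction 0.3) over protein-coding genes, and medians of classes were given 95% bootstrap intervals over genes from 10000 draws, in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6; figures were drawn with matplotlib 3.10.9. Read depth is unknown, so no precision from counting could be given. P-values rest on 2 libraries per group.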

Results

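RNA from HEK293T cells, a line derived from human embryonic kidney and carrying the large T antigen, was sequenced before and after RNA immunoprecipitation (RIP) with an antibody against the Flag epitope. The cells were GFP-positive, and the growth protocol names forced expression of the RNA methyltransferases METTL3, METTL14 and METTL16, while the sample titles call all 4 samples control; which Flag-tagged protein, if any, these cells carried is not given in the sources used here. The samples fell into 2 groups of 2 libraries, input RNA and RNA recovered with the Flag antibody, and the series' design text describes the replicates as biological. Expression was deposited as TPM, an abundance normalised for transcript length and library total, for 26830 gene symbols. TPM keeps no read depth, so the depth of each library is unknown and no counting interval can be given.

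The libraries were dominated by structured non-coding RNA. The 7SL RNA of the signal recognition particle, from RN7SL1 and RN7SL2 together, took 65.97% and 64.8% of all TPM in the inputs and 53.1% and 54.8% in the Flag RIP libraries. These near-identical copies share reads, so their split is uncertain. Other small RNA genes took 19.1% and 19.5% in the inputs and 15.7% and 7.83% in the Flag RIP libraries. The listed rRNA genes held 0.0303% and 0.0738% in the inputs against 0.773% and 1.80% in the Flag RIP libraries, and the ribosomal protein genes 3.62% and 3.80% against 2.71% and 1.08%. The listed genes summed to 976708 and 976011 TPM in the inputs but 795039 and 688863 TPM in Flag RIP 1 and Flag RIP 2, and the remaining 20.5% and 31.1% of those libraries was not analysed here. At least 1 TPM was reached by 10401 and 10535 genes in the inputs, 9685 in Flag RIP 1 and 7553 in Flag RIP 2. Across the 9832 genes with a mean of at least 1 TPM, Pearson's r of the log2 values was 0.994 between the inputs, 0.957 between the Flag RIP libraries and 0.931 to 0.968 between an input and a Flag RIP library; genes are not independent replicates. With 2 libraries against 2, an exact permutation test of a single value cannot go below p = 0.33, so these shares were not tested.

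**Figure D1:**
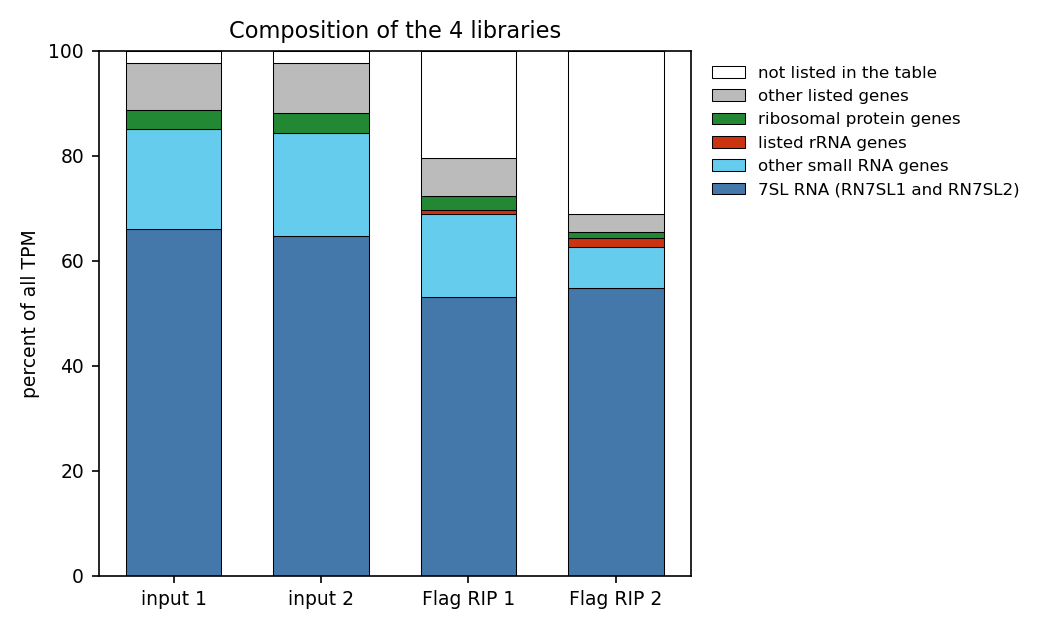
Share of all TPM per library (vertical axis, percent), by class of gene, for the 2 input and the 2 Flag RIP libraries. The part not listed in the table was 2.33% and 2.40% in the inputs and 20.5% and 31.1% in the Flag RIP libraries.

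The comparison of Flag RIP with input asks which transcripts are recovered with the Flag antibody beyond their level in the input. Ribosomal RNA and individual small nucleolar RNAs (snoRNAs), guides of rRNA modification, were higher in the Flag RIP libraries. RNA28S5, the 28S rRNA of the large ribosomal subunit, rose from 86.6 ± 5.34 TPM (SD, n = 2) to 4766 ± 2037 TPM (SD, n = 2), a log2 fold change of 5.70 (SE 0.72, limma adjusted p = 2.19e-12). RNA18S5, the 18S rRNA of the small subunit, was listed at 0 and 418 TPM in the inputs and 3319 and 9806 TPM in the Flag RIP libraries (limma adjusted p = 1.48e-21), and the value of 0 in input 1 can be a failed estimate. RNA45S5, the rRNA precursor, rose from 225 ± 6.58 to 1510 ± 653 TPM (SD, n = 2 each; log2 fold change 2.67, SE 0.73, limma adjusted p = 0.0339). The precursor contains the 18S and 28S sequences, so reads can be shared among these 3 entries and their levels are uncertain. RNA5S9, a 5S rRNA gene at chromosome 1, 228628148 to 228628266, minus strand (GRCh38), was listed at 0 and 0 TPM in the inputs and 37.3 and 0.940 TPM in the Flag RIP libraries, so that Flag RIP 1 set its value (limma adjusted p = 4.45e-16). This p-value rests on the trend over genes of similar level, so the gap between its Flag RIP values did not enter it. 5S genes are repeated and share reads. Relative to the median gene, RNA18S5 stood at 8.76, or 4.45 without input 1 and 13.1 without input 2, which leaves the input value of 0.

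SNORD15B, a box C/D snoRNA in an intron of RPS3 (chromosome 11, 75404421 to 75404566, plus strand), rose from 16.9 ± 1.89 to 262 ± 14.7 TPM (SD, n = 2 each), a log2 fold change of 3.88 (SE 0.81, limma adjusted p = 4.15e-04). SNORD56, which overlaps an annotated exon of NOP56 (chromosome 20, 2656624 to 2656694, plus strand), rose from 1.76 ± 0.290 to 15.1 ± 7.87 TPM (log2 fold change 2.46, SE 0.51, limma adjusted p = 3.58e-04). The abundant box H/ACA snoRNA genes SNORA73A and SNORA73B, named after their values were seen, stood at 81.6 ± 1.82 and 83.4 ± 3.20 TPM in the inputs and at 370 ± 14.9 and 394 ± 1.61 TPM in the Flag RIP libraries, but missed the threshold (limma adjusted p = 0.219 and 0.210). These p-values also rest on the trend, not on the small spread of these genes.

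Several structured RNAs transcribed by RNA polymerase III and single mRNAs were lower. RPPH1, the RNA of RNase P (chromosome 14, 20343075 to 20343407, minus strand), fell from 72487 ± 3877 to 27499 ± 19352 TPM (SD, n = 2 each; log2 fold change -1.60, SE 0.22, limma adjusted p = 2.71e-10). RNU6ATAC, the U6atac RNA of the minor spliceosome (chromosome 9, 134164439 to 134164564, minus strand), was at 1021 and 816 TPM in the inputs and 412 and 39.3 TPM in the Flag RIP libraries (log2 fold change -2.82, SE 0.78, limma adjusted p = 0.0368). The vault RNA gene VTRNA1-3 (chromosome 5, 140726158 to 140726246, plus strand) fell from 75.3 ± 17.6 to 11.1 ± 5.81 TPM (log2 fold change -2.72, SE 0.74, limma adjusted p = 0.0333). SNORD4A, in an intron of RPL23A (chromosome 17, 28722582 to 28722653, plus strand), fell and was listed at 8.37 and 14.95 TPM in the inputs and 2.82 and 0 TPM in the Flag RIP libraries (limma adjusted p = 2.70e-06), and the histone H4 gene HIST1H4K (chromosome 6, 27831216 to 27831527, minus strand) at 9.53 and 14.7 TPM in the inputs and 6.30 and 0 TPM in the Flag RIP libraries (limma adjusted p = 0.00118). RN7SK, the 7SK RNA that restrains the elongation factor P-TEFb (chromosome 6, 52995621 to 52995948, plus strand), was at 63892 ± 1004 and 37208 ± 21156 TPM (log2 fold change -0.91, limma adjusted p = 0.00393). Its value relative to the median gene was -0.27 and turned to 0.33 under quantile normalization. Without Flag RIP 1 and without Flag RIP 2, values relative to the median gene were -3.52 and -0.87 for RNU6ATAC (-2.19 with both), -2.70 and -0.54 for HIST1H4K (-1.61 with both), -1.41 and -0.53 for RPPH1 (-0.97 with both) and -0.54 and -0.012 for RN7SK.

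**Figure D2:**
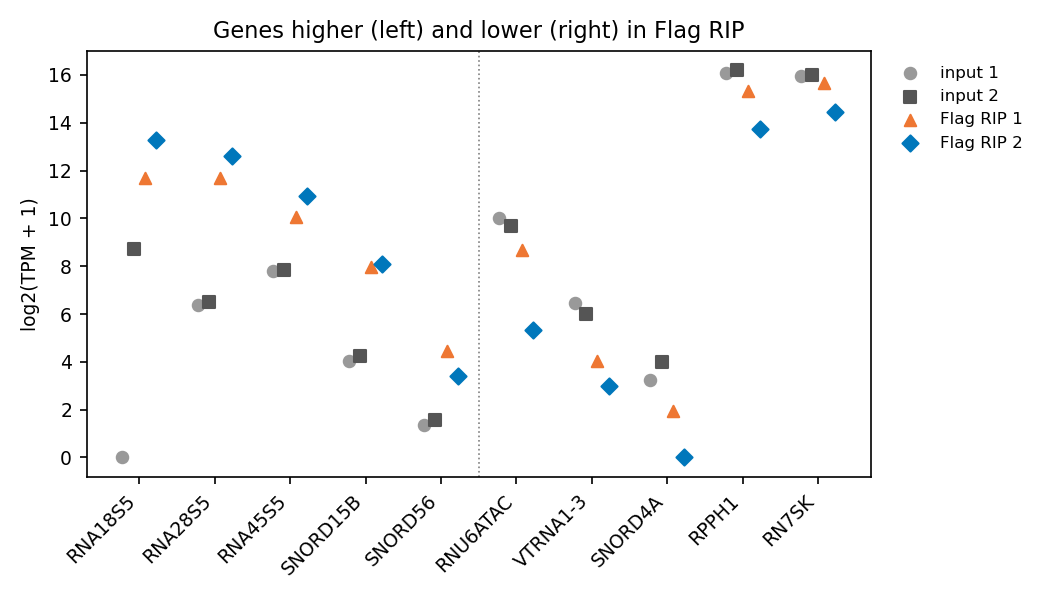
Expression of 10 genes past the test's threshold, as log2(TPM + 1) (vertical axis), with 1 point per library: circles and squares for inputs 1 and 2, triangles and diamonds for Flag RIP 1 and 2. RNA28S5 stands at 82.8 and 90.4 TPM in the inputs and 3326 and 6207 TPM in the Flag RIP libraries; RPPH1 at 69746 and 75229 against 41183 and 13816 TPM.

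In all, limma on log2(TPM + 1) called 31 genes higher and 48 lower in Flag RIP at an adjusted p under 0.05 among 9832 genes. A mean of at least 5 TPM was reached by 7 of the 31 and 6 of the 48, against 3588 of the 9832. Most calls were thus of genes near the filter's limit of 1 TPM, where p rests on the trend and not on the gene's own spread. Small RNA names made up 27 of the 31 and 21 of the 48. The 27 were 11 miRNA precursors, 6 box H/ACA snoRNAs, 6 box C/D snoRNAs and 4 rRNA genes. Of these classes 4, 2, 5 and 0 members were called lower. RNU1-1, RNU1-2, RNU1-3, RNU1-4 and RNVU1-18, copies of the U1 RNA, carried identical values (5.01 and 5.40 TPM in the inputs, listed at 0 in both Flag RIP libraries) and are not independent; with such rows merged, 30 higher and 44 lower sets of values remained. The median gene lay at a log2 fold change of -0.64, and 8390 genes had both Flag RIP values below both inputs, against 115 with both above; chance gives 33.3% for either direction together, and 86.5% was seen. Changes are therefore also given relative to this median. With each library centred on its median, 0 genes were called higher and 0 lower by limma (smallest adjusted p = 0.0564), with 984 higher and 1108 lower at an unadjusted p under 0.05, against 75 higher and 1727 lower without centring; quantile normalization called 1 gene higher, SNORD56, and 0 lower. Centring moves every fold up by about the same amount. For the 31 higher genes the median log2 fold change was 1.64 before and 2.28 after, with a median SE of 0.33 and 0.58. For the 48 lower genes it was -1.30 and -0.66, with a median SE of 0.30 and 0.24. Centring also took limma's prior degrees of freedom from infinite to 2.84, so fewer degrees of freedom stood behind each p and the gene's own spread entered it. Rescaling after leaving out small RNAs and the 20 highest genes called 0 in both directions, with 1974 genes at an unadjusted p under 0.05. Single libraries also set the counts: without input 1, 0 genes were higher and 7 lower; without input 2, RNA18S5 alone was higher and 7 were lower; without Flag RIP 1, 142 were higher and 9618 lower; without Flag RIP 2, 279 were higher and 6294 lower. In the last 2 fits the lone Flag RIP library is assumed to vary as little as the inputs do.

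The 3 methyltransferase genes named in the growth protocol were at modest levels and did not pass the test. METTL16, which methylates U6 RNA and MAT2A mRNA, stood at 4.80 ± 0.346 TPM in the inputs and 5.56 ± 0.191 TPM in the Flag RIP libraries (SD, n = 2 each; limma adjusted p = 0.730). METTL3 stood at 5.37 ± 0.127 and 3.66 ± 1.16 TPM, and its partner METTL14 at 2.14 ± 0.240 and 1.45 ± 0.997 TPM (limma adjusted p = 0.379 and 0.308). Relative to the median gene, their log2 fold changes were 0.82, 0.16 and 0.22, or 1.19, 0.25 and 0.14 without Flag RIP 1 and 0.43, 0.063 and 0.29 without Flag RIP 2. With no filter on low values they were 0.46, -0.19 and -0.14, so the direction turned for METTL3 and METTL14. As a list they missed the threshold (camera adjusted p = 0.146). Of textbook METTL16-bound RNAs, MAT2A was at 20.2 ± 0.940 and 15.6 ± 4.21 TPM and MALAT1 at 29.8 ± 1.97 and 19.8 ± 0.955 TPM, with relative log2 fold changes of 0.26 and 0.074 (limma adjusted p = 0.595 and 0.469). Without Flag RIP 1 these were 0.34 and 0.37, and without Flag RIP 2 0.16 and -0.24, so the direction for MALAT1 differed between the Flag RIP libraries. Without a filter both were negative (-0.10 and -0.28), and at a pseudocount of 5 MALAT1 was at -0.17.

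The gene lists were compared with all other genes by camera; 4 of the 24 lists with at least 3 tested members passed, and 0 of them with an estimated correlation. The list of small nuclear, nucleolar and Cajal body RNAs stood above other genes as a whole: of 181 tested members, 153 lay above the median gene and 28 below, with a median of 1.15 relative to it (camera adjusted p = 8.19e-128, or 0.303 with an estimated correlation, and fry p = 0.281). The nucleolar and Cajal body RNAs carried the higher position, with 148 of 168 above in a set that adds SCARNA9L and SCARNA26A to those of the list. Spliceosomal RNAs, a class formed later that adds RNVU1 genes from outside the list, did not share it, with 10 of 22 above and a median of -0.11. Over all genes 12 members rose and 12 fell, and adjusted over the list alone 39 rose and 20 fell; after median centring, 99 rose and 8 fell when adjusted over the list alone. SNORD15B was among those that rose, and SNORD4A, RNU6ATAC and RNU1-1 among those that fell. After centring, 122 members had both Flag RIP values above both inputs and 15 both below. These were 67.4% and 8.29% of the list, against 30.3% and 29.2% of all tested genes and 16.7% in each direction by chance. The filter kept 181 of 477 listed members by their mean over all libraries. Members near 0 in the inputs can pass it through high Flag RIP values, which raises the shares above. The members' medians were 1.06 in Flag RIP 1 and 1.31 in Flag RIP 2.

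Messenger RNAs of the translation machinery stood below other genes. Of 77 cytosolic ribosomal protein genes, 75 lay below the median gene, all but RPL35A and RPL39, with a median of -0.49 (camera adjusted p = 7.39e-18; adjusted p = 0.895 with an estimated correlation; fry p = 0.237). No single member passed the test over all genes or adjusted over the list alone. RPS2 was at 2238 ± 23.1 TPM in the inputs and 996 ± 506 TPM in the Flag RIP libraries, RPL39 at 1241 ± 95.1 and 914 ± 583 TPM. The medians were -0.18 in Flag RIP 1 and -0.82 in Flag RIP 2. Of 35 translation factor genes, 32 lay below the median gene, all but EIF1AX, EIF2S1 and EIF4E, with a median of -0.30 (camera adjusted p = 1.86e-04; adjusted p = 0.895 with an estimated correlation); 0 passed singly over all genes or adjusted over the list alone. EEF1A1, an elongation factor, was at 1039 ± 47.8 and 524 ± 267 TPM and EEF1G at 722 ± 26.3 and 330 ± 170 TPM. The translation factor call ended in several settings, among them a pseudocount of 0.1 (adjusted p = 0.448) and without Flag RIP 2 (mean against all other genes -0.16, from -0.30; adjusted p = 0.0827).

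Of 12 abundant RNAs of ribonucleoprotein particles, VTRNA1-3, RPPH1 and RN7SK fell and 0 rose over all genes, and 6 fell adjusted over the list alone, or 1, VTRNA1-3, after median centring (median relative to the median gene -0.20, camera adjusted p = 0.00796; adjusted p = 0.895 with an estimated correlation). Its mean against all other genes was -0.36, or -0.19 (adjusted p = 0.240) without Flag RIP 2. After median centring the list was not called (adjusted p = 0.560). RN7SL1 was at 327086 ± 5402 TPM in the inputs and 257138 ± 4549 TPM in the Flag RIP libraries, RN7SL2 at 326602 ± 3069 and 282284 ± 7119 TPM, and RMRP, the RNA of RNase MRP, at 15629 ± 379 and 17138 ± 3265 TPM; these 3 did not pass (limma adjusted p = 0.0793, 0.270 and 0.709). At a pseudocount of 5, RN7SL1 and RN7SL2 were called lower (limma adjusted p = 5.65e-41 and 2.51e-15). The median gene lay at -0.32 in that setting, and relative to it they stood at -0.028 and 0.11, so neither fell more than the typical gene by much. Fits without 1 Flag RIP library also gave calls, lower for RN7SL1 and RN7SL2 and higher for RMRP. With 1 library left out at a time, values relative to the median gene ran from -0.085 to 0.66 for RN7SL1, 0.044 to 0.80 for RN7SL2 and 0.60 to 0.91 for RMRP.

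**Figure D3:**
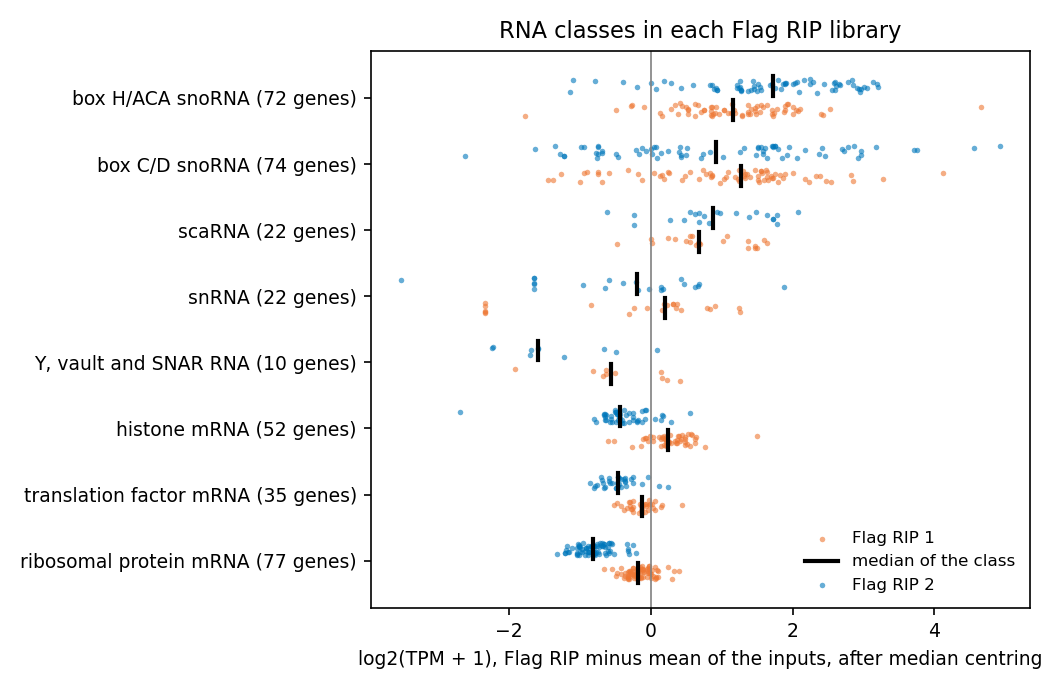
Log2(TPM + 1) in each Flag RIP library minus the mean of the inputs, after median centring (horizontal axis), with 1 point per gene and library and a bar at each median; the split of small RNAs into classes was chosen after the data were seen. The medians in Flag RIP 1 and Flag RIP 2 were 1.16 and 1.73 for box H/ACA snoRNAs and -0.18 and -0.82 for ribosomal protein mRNAs.

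The other gene lists did not pass camera's threshold, and their values are given as log2 fold changes relative to the median gene, with camera's adjusted p. Other m6A writers, readers and erasers had a median of 0.015 over 18 members (adjusted p = 0.524), with IGF2BP1 at -0.31 and ALKBH5 at -0.38. Its mean was -0.065, below the median gene, as was the direction of the test. For mitochondrial ribosomal proteins, the median of 77 members was -0.13 (adjusted p = 0.0941), and MRPL37 and MRPL12 lay at -0.33 and -0.59. Nuclear-encoded respiratory chain subunits had a median of -0.067 over 76 members (adjusted p = 0.209), with COX7C at 0.058 and COX6A1 at 0.036. For replication-dependent histones, the median of 52 members was -0.12 (adjusted p = 0.331), and HIST1H3B and HIST1H1C lay at 0.25 and -0.16. SnoRNA host transcripts had a median of -0.12 over 20 members (adjusted p = 0.176), with SNHG5 at -0.56 and GAS5 at -0.59. Nuclear long non-coding RNAs had a median of 0.074 over 9 members (adjusted p = 0.331), with NORAD at -0.24 and MALAT1 at 0.074. SR proteins and CLK kinases had a median of 0.092 over 24 members (adjusted p = 0.209), with SRRM2 at 0.056 and SRSF3 at -0.13. For C2H2 zinc finger genes, the median of 234 members was 0.12 (adjusted p = 0.140), and ZNF703 and ZNF664 lay at -0.65 and -0.33. Endoplasmic reticulum import and folding had a median of -0.031 over 25 members (adjusted p = 0.524), with CANX at -0.12 and SSR2 at -0.20. Among histone genes HIST1H4K fell and 0 rose, over all genes and adjusted over the list alone. Among snoRNA host transcripts SNHG25 fell (3.39 and 2.70 TPM in the inputs and 0 and 1.10 TPM in the Flag RIP libraries, limma adjusted p = 1.19e-04) and 0 rose. Its relative value was -0.84, or 0.044 without Flag RIP 1 and -1.73 without Flag RIP 2. Those of SNHG5 and GAS5 were -1.09 and -0.96 without Flag RIP 1 and -0.042 and -0.23 without Flag RIP 2. Of the remaining members of these lists, 0 passed singly over all genes or adjusted over the list alone. The medians of the host transcripts and the histones were -0.12 and -0.12, and the histone median was 0.25 in Flag RIP 1 and -0.44 in Flag RIP 2.

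Large surface and matrix proteins had a median of 0.043 over 25 members (adjusted p = 0.473), with NOTCH2 at -0.01 and PTPRF at -0.34. For the heat shock response, the median of 13 members was -0.14 (adjusted p = 0.285), and HSPA8 and HSPD1 lay at -0.046 and -0.32. Immediate early genes had a median of -0.13 over 10 members (adjusted p = 0.285), with MYC at -0.42 and JUND at -1.003. For the integrated stress response, the median of 14 members was -0.24 (adjusted p = 0.0995), and ATF4 and PHGDH lay at -0.70 and -0.22. Mitotic genes had a median of -0.051 over 20 members (adjusted p = 0.528), with TOP2A at -0.015 and BIRC5 at -0.32. For DNA replication, the median of 25 members was -0.094 (adjusted p = 0.209), and PCNA and MCM7 lay at 0.071 and -0.12. The proteasome had a median of -0.14 over 34 members (adjusted p = 0.140), with PSMB4 at -0.26 and PSMA7 at -0.61. For glycolysis, the median of 15 members was -0.26 (adjusted p = 0.107), and GAPDH and LDHB lay at -0.33 and -0.26. Sterol synthesis had a median of -0.087 over 21 members (adjusted p = 0.410), with INSIG1 at -0.14. For the tubulin and actin cytoskeleton, the median of 17 members was -0.32 (adjusted p = 0.0814), and ACTG1 and ACTB lay at -0.39 and -0.31. No member of these 10 lists passed singly over all genes; adjusted over the list alone, 3 immediate early genes (JUND, IER2 and IER5) and 1 gene of the integrated stress response (DDIT3) fell; after median centring these were 1, JUND, and 0. Under 1 or more of the scaling alternatives the value changed sign for RN7SL1, RPL39, HIST1H1C, SRSF3, CANX, SSR2, NOTCH2, HSPA8, TOP2A, MCM7, GAPDH and INSIG1, and the list mean changed sign for the m6A machinery, the respiratory chain, histones, endoplasmic reticulum import, mitotic genes, DNA replication and the proteasome.

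Several of these lists passed camera's threshold in other settings, with means given against all other genes. Under median centring, C2H2 zinc finger genes stood at 0.082 (adjusted p = 0.0134), glycolysis at -0.21 (adjusted p = 0.0134), the integrated stress response at -0.23 (adjusted p = 0.0367) and the tubulin and actin cytoskeleton at -0.23 (adjusted p = 0.0367). With an estimated correlation, 0 lists passed after centring (adjusted p = 0.874 for each of these 4); the settings that follow were run at the preset correlation alone. At a pseudocount of 5, glycolysis stood at -0.32 (adjusted p = 0.0287), the tubulin and actin cytoskeleton at -0.33 (adjusted p = 0.0348) and DNA replication at -0.18 (adjusted p = 0.0348). SR proteins and CLK kinases, at 0.13 in the main fit, stood at 0.24 (adjusted p = 2.39e-04) under quantile normalization and 0.30 (adjusted p = 7.08e-04) when rescaled without small RNAs and the 20 highest genes. That rescaling also placed the respiratory chain at 0.073 (adjusted p = 0.0465), histones at 0.15 (adjusted p = 0.0210) and endoplasmic reticulum import at 0.12 (adjusted p = 0.0210), opposite to the main fit. Without a filter, zinc fingers at -0.0027 (adjusted p = 0.0111) and large surface and matrix proteins at -0.17 (adjusted p = 0.00515) were opposite too. Without Flag RIP 1, lower calls were made for mitochondrial ribosomal proteins, the respiratory chain, histones, endoplasmic reticulum import, the integrated stress response, the proteasome, glycolysis and the tubulin and actin cytoskeleton, and a higher call for zinc fingers. Without Flag RIP 2, the respiratory chain at 0.16 (adjusted p = 0.00801) and histones at 0.25 (adjusted p = 1.28e-04) were called higher.

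Of the markers of other cell types, HBB and ACTA2 reached 1 TPM in at least 1 library. HBB, the beta chain of haemoglobin (chromosome 11, 5225464 to 5229395, minus strand), was at 0.420 and 0.0700 TPM in the inputs and 3.35 and 5.35 TPM in the Flag RIP libraries, and rose by a log2 fold change of 2.09 (SE 0.30, limma adjusted p = 3.26e-09), while HBA1 was listed at 0 in all 4 libraries and HBA2 reached at most 0.45 TPM. Of 15 leukocyte and 10 hepatocyte markers, 0 reached 1 TPM in any library. ACTA2, the smooth muscle actin used here as a fibroblast marker, was at 4.57 ± 0.134 TPM in the inputs and 2.35 ± 1.44 TPM in the Flag RIP libraries (limma adjusted p = 0.271), and the other 9 fibroblast markers stayed under 1 TPM. MYO5B, a myosin motor gene named after its values were seen, was at 0.620 and 0.620 TPM in the inputs and 4.46 and 4.33 TPM in the Flag RIP libraries (limma adjusted p = 1.26e-04). Genes encoded by mitochondrial DNA were not analysed here.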

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

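Counts and calls changed with scaling, the filter on low values and single libraries, and depth is unknown. The higher position of the list of small nuclear, nucleolar and Cajal body RNAs and the lower position of ribosomal protein genes kept their direction and camera's threshold under each setting that gave them a value (small RNAs are left out of one), with means of 0.40 to 1.48 and -0.81 to -0.17 against all other genes. The first was carried by nucleolar and Cajal body RNAs and not by spliceosomal RNAs. Neither held with an estimated correlation. The labels state no pairing of same-numbered libraries. Their deviations had a correlation of -0.038 across genes, which rests on 2 pairs and cannot show whether they shared a source. With the replicate block 15 genes were higher and 11 lower, all 26 among the 79. Without a trend in eBayes 38 genes were higher and 59 lower, and 41 of these 97 were among the 79; of the 83 and 105 called at pseudocounts of 0.1 and 5, 59 and 76 were, and of the 53 with robust eBayes, 53. Over the alternatives fixed beforehand, gene values kept direction and side of the threshold in 689 cases, crossed it in the same direction in 176 and changed sign in 77, of which 14 also crossed it; for list means these were 292, 30, 34 and 7. Where fewer genes or libraries were used this follows from the setting; elsewhere the cause was not tested. List means are against all other genes and gene values relative to the median gene, both in log2.

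With a pseudocount of 0.1, 2 lists were called, and list means were -0.15 for translation factors, 0.046 for respiratory chain, 0.070 for histones, -0.17 for ribonucleoprotein RNAs, 0.088 for ER import and 0.051 for mitotic genes, and relative values were 0.041 for HIST1H1C, 0.035 for SRSF3, 0.064 for CANX, 0.13 for NOTCH2, 0.15 for HSPA8, 0.16 for TOP2A, 0.051 for MCM7 and 0.024 for INSIG1. At a pseudocount of 5, list means were -0.59 for ribonucleoprotein RNAs, and relative values were -0.17 for MALAT1, -0.28 for RPL39, -0.22 for COX7C, -0.24 for COX6A1, -0.066 for HIST1H3B, -0.21 for SRRM2, -0.19 for PCNA and -0.028 for RN7SL1. With no filter on low values, 0 genes were higher, 0 genes were lower and 8 lists were called, and list means were -0.65 for ribonucleoprotein RNAs, -0.14 for SR proteins and CLK kinases, -0.0027 for zinc fingers and -0.17 for large surface and matrix proteins, and relative values were -0.19 for METTL3, -0.28 for MALAT1, -0.10 for MAT2A, -0.32 for RPL39, -0.30 for COX7C, -0.32 for COX6A1, -0.11 for HIST1H3B, -0.30 for SRRM2, -0.28 for PCNA, -0.14 for METTL14 and -0.064 for RN7SL1. For genes with a mean of at least 5 TPM, 5 genes were higher (RNA18S5, RNA28S5, RNA5S9, SNORD15B and SNORD56), 4 genes were lower (HIST1H4K, RN7SK, RPPH1 and SNORD4A) and 2 lists were called, and list means were -0.19 for translation factors, 0.040 for respiratory chain, 0.076 for histones, -0.21 for ribonucleoprotein RNAs, -0.12 for zinc fingers, 0.082 for ER import, 0.043 for mitotic genes and 0.019 for DNA replication, and relative values were 0.0062 for HIST1H1C, 0.031 for SRSF3, 0.043 for CANX, 0.16 for NOTCH2, 0.12 for HSPA8, 0.15 for TOP2A, 0.042 for MCM7 and 0.027 for INSIG1. For genes with at least 1 TPM in every library, 3 genes were higher (RNA28S5, SNORD15B and SNORD56) and 1 gene was lower (RPPH1), and relative values were 0.029 for NOTCH2 and 0.024 for TOP2A. Under quantile normalization, 1 gene was higher (SNORD56) and 0 genes were lower, and list means were 0.010 for m6A machinery, 0.044 for respiratory chain, 0.053 for histones, -0.48 for ribonucleoprotein RNAs, 0.089 for ER import, 0.068 for mitotic genes and 0.014 for DNA replication, and relative values were 0.33 for RN7SK, -0.63 for RPL39, 0.12 for HIST1H1C, 0.033 for SRSF3, 0.037 for CANX, 0.18 for NOTCH2, 0.080 for HSPA8, 0.17 for TOP2A, 0.037 for MCM7, 0.058 for GAPDH, 0.051 for INSIG1 and -0.025 for RN7SL1. Under median centring, 0 genes were higher, 0 genes were lower and 7 lists were called, and list means were -0.36 for ribonucleoprotein RNAs. Rescaled without small RNAs and the 20 highest genes, 0 genes were higher and 0 genes were lower, and list means were 0.023 for m6A machinery, -0.10 for translation factors, 0.073 for respiratory chain, 0.15 for histones, 0.12 for ER import, 0.074 for mitotic genes, 0.013 for DNA replication and 0.017 for the proteasome, and relative values were 0.063 for HIST1H1C, 0.053 for SRSF3, 0.084 for CANX, 0.00042 for SSR2, 0.15 for NOTCH2, 0.17 for HSPA8, 0.17 for TOP2A, 0.070 for MCM7 and 0.041 for INSIG1. With the replicate number as a block, 15 genes were higher and 11 genes were lower. With robust eBayes, 16 genes were higher and 37 genes were lower. At an adjusted p under 0.01, 29 genes were higher and 27 genes were lower.

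Leaving out 1 library at a time gave 0 to 279 for the count higher, 7 to 9618 for the count lower and 3 to 13 for lists called; list means ran from -0.53 to -0.19 for ribonucleoprotein RNAs, -0.40 to -0.16 for translation factors, -0.29 to 0.032 for mitochondrial ribosomal proteins, -0.34 to 0.16 for respiratory chain, -0.40 to 0.25 for histones, -0.017 to 0.19 for zinc fingers, -0.24 to 0.13 for ER import, -0.025 to 0.15 for large surface and matrix proteins, -0.13 to 0.017 for mitotic genes and -0.33 to 0.047 for the proteasome, and gene values from -0.32 to 0.38 for RPL39, -0.13 to 0.61 for HIST1H3B, -0.015 to 0.0029 for NOTCH2, -0.17 to 0.13 for TOP2A, -0.56 to 0.67 for COX7C, -0.33 to 0.40 for COX6A1, -1.73 to 0.044 for SNHG25, -0.10 to 0.23 for PCNA, -0.24 to 0.37 for MALAT1, -0.45 to 0.12 for HIST1H1C, -0.045 to 0.15 for SRRM2, -0.31 to 0.035 for SRSF3, -0.29 to 0.040 for CANX, -0.14 to 0.038 for HSPA8, -0.30 to 0.013 for INSIG1 and -0.085 to 0.66 for RN7SL1. Some values kept their sign but moved widely, among them -0.53 to -0.0080 for PSMB4, -0.86 to -0.36 for PSMA7, -0.52 to -0.014 for LDHB and -0.48 to -0.19 for GAPDH. The list mean of glycolysis ran from -0.32 to -0.11. A Flag RIP library left alone is assumed to vary like the inputs.

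The following settings were chosen after seeing the data. Scaled over genes other than small RNAs, 3 genes were higher (SNORA6, SNORD33 and SNORD56) and 6 genes were lower, and list means were -0.11 for translation factors and -0.14 for ribonucleoprotein RNAs. With listed genes rescaled to 1 common total, 83 genes were higher and 59 genes were lower, and list means were -0.26 for ribonucleoprotein RNAs. Centred and with the replicate block, 346 genes were higher, 393 genes were lower and 9 lists were called, and list means were -0.36 for ribonucleoprotein RNAs. Centred with a pseudocount of 0.1, 1 gene was higher (SNORD56) and 0 genes were lower, and list means were -0.17 for ribonucleoprotein RNAs. Centred without Flag RIP 1, 3187 genes were higher, 3527 genes were lower and 15 lists were called, and list means were -0.53 for ribonucleoprotein RNAs. Centred without Flag RIP 2, 2105 genes were higher and 2368 genes were lower, and list means were -0.19 for ribonucleoprotein RNAs.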

Other observations

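The small RNA classes, the comparison of snoRNAs with their host genes, and the tests on snoRNAs, on the pseudocount, on the length of the principal isoform and on haemoglobin genes were chosen after the results were seen; the tests on GC and on the longest transcript were written down before their results were seen.

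Medians of small RNA classes lay on both sides of the median gene in the Flag RIP libraries. Box H/ACA snoRNAs, which guide pseudouridylation, had a median of 1.45 relative to the median gene over 72 genes, 67 of them above it, and 64 had both Flag RIP values above both inputs after centring (88.9%, against 30.3% of all tested genes and 16.7% by chance). Box C/D snoRNAs, which guide 2'-O-methylation, had a median of 1.07 over 74 genes, 61 above, and 37 did not overlap in that direction. Small Cajal body RNAs had a median of 0.90, with 20 of 22 above. Spliceosomal RNAs spread both ways, with 10 of 22 above and a median of -0.11. The identical rows RNU1-1 to RNU1-4 and RNVU1-18 count separately among those below, and no U7 gene was among those tested. Y, vault and SNAR RNAs had a median of -1.11, with 9 of 10 below. The 4 tested rRNA genes had a median of 5.04. The 33 tested miRNA precursor genes had a median of 0.77. It turned to -0.20 when TPM were scaled over genes other than small RNAs, and to -0.55 with a pseudocount of 0.1 as well. These 33 were what the filter kept of 1835 listed precursor genes. The filter used the mean over all libraries, so a gene near 0 in the inputs can pass it through high Flag RIP values. This holds for snoRNAs too, of which it kept 72 of 133 box H/ACA and 74 of 296 box C/D genes. With an estimated correlation, camera's adjusted p over these 7 classes was 0.00410 for box H/ACA, 0.0499 for box C/D, 0.0701 for Cajal body RNAs, 0.303 for spliceosomal RNAs, 0.158 for Y, vault and SNAR RNAs, 0.00410 for rRNA and 0.0241 for miRNA precursors. After median centring none of the 7 passed, the lowest being 0.156.

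Most snoRNAs and Cajal body RNAs stood above the genes that enclose them. For 130 of them an annotated gene on the same strand enclosed the small RNA and was itself tested, and 117 stood above that gene in relative log2 fold change. Their median was 1.26, against -0.16 for the 94 distinct enclosing genes. Among 9026 protein-coding genes, the change went with base composition and transcript length. Spearman's rho across genes between GC percent and the change was -0.52 with TPM scaled over genes other than small RNAs. On median-centred values it was -0.61 in Flag RIP 1 and -0.30 in Flag RIP 2. For the length of the longest transcript rho was 0.26 on the scaled values, and 0.13 in Flag RIP 1 and 0.34 in Flag RIP 2 on the centred values. As the scales differ, these values are not directly comparable. Genes are not independent replicates. On the scaled values, the fifth of genes lowest in GC, up to 40.5%, had a median of 0.16 and the highest, from 57.4%, -0.24.

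The position of snoRNAs and Cajal body RNAs above other genes was weighed against 3 technical explanations. GC content, which went with the change among protein-coding genes, was not tested for these RNAs and stays open. If short features gained TPM, other short non-coding RNAs would rise alike, but the 72 other tested genes with small RNA names, miRNA precursors and 5S included, had a median of -0.12 (95% bootstrap interval -0.35 to 0.34), below the 1.23 (1.07 to 1.40) of the 168 snoRNAs and Cajal body RNAs. These 72, with identical U1 rows counted separately, went both ways, 34 above and 38 below the median gene, with an upper quartile of 0.87. With a mean of at least 10 TPM in the inputs, 33 had a median of -0.12 against 1.52 for 39 snoRNAs and Cajal body RNAs. Unless these sets differ in GC content, short length alone therefore does not account for the position. The miRNA precursors had a median of 0.77, but the 4 at that input level had a median of -0.052, with 2 above and 2 below. An effect on precursors low in the inputs stays open. Greater carry-over of all RNA without a poly(A) tail would raise the histone genes, whose median was -0.12 (-0.15 to 0.034). After median centring the Flag RIP libraries disagreed on the histones, with medians of 0.25 (0.20 to 0.38) and -0.44 (-0.49 to -0.33). The log2(TPM + 1) scale understates the change of low genes, so part of this gap can come from the scale. With TPM scaled over genes other than small RNAs, the histone median was 0.090 (0.053 to 0.23), against 1.53 (1.24 to 1.75) for snoRNAs and Cajal body RNAs. Against all other genes the histone mean was 0.25 without Flag RIP 2. It was 0.15 when rescaled without small RNAs, where camera called the histones higher. In both libraries the histones lay below the snoRNAs and Cajal body RNAs, at 1.16 (0.92 to 1.35) and 1.46 (1.24 to 1.62). Unless GC content sets them apart, carry-over as the whole cause is argued against. A smaller part in Flag RIP 1 and the rise of the rRNA genes stay open. With noise near the floor as the cause, well-expressed members would agree less, but of 39 with a mean of at least 10 TPM in the inputs, 35 (89.7%, Wilson 95% interval 76.4 to 95.9%) had both Flag RIP values above both inputs after centring, against 5.94% of the 2121 tested genes at that level. Genes with a mean of at least 5 TPM had a median log2 fold change of -0.80, against -0.64 for all tested genes. Centring on all genes therefore places well-expressed genes low, and the 5.94% overstates the contrast. These intervals treat genes of the same 4 libraries as independent. Recovery through the Flag antibody, through the beads alone and through cross-linking or sonication stay open, since no library with another antibody or with beads alone was analysed here.

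The lower position of ribosomal protein mRNAs was weighed against the pseudocount, GC content and transcript length. Against all other genes their mean was -0.49; a pseudocount of 0.1 alone took it to -0.30, and scaling TPM over genes other than small RNAs alone to -0.27. With both, the mean relative to the median gene was -0.27 (SE 0.022), so after scaling the smaller pseudocount moved it little, and part of the value remained. Among protein-coding genes, scaled alike with a pseudocount of 1, it was -0.25 before correction, -0.24 (SE 0.024) after the GC trend was removed, -0.17 (SE 0.023) after the trend with the longest annotated transcript was removed and -0.22 after both. The longest transcript overstates the length of many ribosomal protein mRNAs (median 1857 nt, or 1017 nt for the principal isoform); with the principal isoform's length the mean was -0.18 (SE 0.023). For translation factors the means after the GC trend and the longest-transcript trend were removed were -0.12 and -0.082, from -0.11 before. These SE measure the spread over genes of the same 4 libraries, and the position was more marked in Flag RIP 2 than in Flag RIP 1. No biological explanation was tested.

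HBB in both Flag RIP libraries may come from another source than red blood cells, which carry alpha chain transcripts too: HBA1 and HBA2 together reached at most 13.4% of HBB there. HBB is at few TPM, and no other source was tested.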
